A study of Penicillium oxalicum with 12 samples.

How the data were processed

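RNA from mycelia of the filamentous fungus Penicillium oxalicum was profiled in 4 strains with 3 libraries each, 12 in all. Per the labels, the strains were the wild type 114-2 (WT), a laeA deletion strain (DlaeA) and 2 strains with a point mutation in histone H2B, in which lysine 123 (H2BK123A) or lysine 131 (H2BK131A) was replaced by alanine. Per the labels' protocols, conidia were pre-cultured for 22 h at 30 °C with 2% glucose. The washed mycelia were then moved to Mandel's medium with 2% glucose and harvested after 24 h. Groups and replicate numbers were taken from the sample titles. Nothing in the labels says that the 3 libraries of a strain came from separate cultures, so the p-values measure only the spread between these libraries, which may be technical.

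The labels' protocols describe digital gene expression libraries, in which cDNA made on oligo(dT) beads was cut with the enzymes NlaIII and MmeI so that each transcript gives a short tag next to a CATG site. The deposited table, in contrast, holds 1 FPKM value (fragments per kilobase of transcript, scaled to the mapped fragments of the library) per gene and library with 2 decimals, per the file headers. A per-kilobase unit is unusual for such tags, whose number does not depend on transcript length. The aligner, the counting tool, the genome build and the gene models are not given in the sources used here. Comparisons of a gene between libraries do not depend on its length, while comparisons of FPKM between genes do. The share of a library's FPKM held by its 10 highest genes is such a comparison and depends on the lengths the authors used.

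The absolute depth is unknown because the table holds no counts. Low FPKM values fell on steps that whole reads would give. Of 1469 values of 238 low genes, 85.8% were whole multiples within 0.1 read, and the value of 1 read differed between libraries by a factor of 1.0 to 1.028, from 27 to 44 low genes per library. The step of a gene was set from its own values close to its lowest, which were then counted too, so part of this share is fixed by the method. A large difference between libraries could not show in the factor either. Within these limits depth appeared similar between libraries, and a count model was not used. FPKM sums per library ranged from 709483.7 to 764698.6.

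The deposited FPKM were transformed to log2(FPKM + 1) and tested with limma 3.58.1 in R 4.3.3 (a linear model with strain as the only term over all 12 libraries, empirical Bayes with a mean-variance trend, 8 residual degrees of freedom, two-sided). Genes with an FPKM of at least 1 in at least 3 libraries were tested, 9431 of the 9931 genes, and 500 were not. The Benjamini-Hochberg adjustment was applied within each of 6 comparisons: each mutant with WT, and each pair of mutants. A gene was called at an adjusted p under 0.05. Fold changes are log2 differences of FPKM + 1 ± SE, which understates the change of low genes. On simulated data with 200 of 9431 genes changed, the fit for DlaeA against WT recovered 22.4%, 83.6% and 98.5% of genes changed by log2 folds of 0.5, 1 and 2. The corresponding shares were 26.9%, 86.6% and 97% for H2BK123A and 26.9%, 88.1% and 97% for H2BK131A. False calls made up 8.1%, 4.1% and 6% of the calls in these 3 simulations. Every library was simulated with the spread pooled over strains, whereas WT varied more (median SD per gene 0.223 on the log2 scale, against 0.111 to 0.124 in the mutants). Far more genes were also called in the data than were changed here. These rates may therefore not hold for the comparisons with WT.

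Gene names came from the descriptions in the deposited table: 680 genes with a usable description from a protein database and 4914 with a single KEGG name, 5075 genes together. Another 817 genes with more than 1 KEGG name were not given one. The reference table used here holds 0 loci with PDE identifiers, so it added no names, and genomic coordinates are not used here. Genes are given by locus identifier, and a name means only that the gene is described so. No description names laeA. The design had provided for identifying laeA by a description, and the locus PDE_00584, recalled as laeA from published work before the data were examined, was used in its place. The H2B gene is PDE_01489 by its description.

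Before the data were examined, the tests, the filter, the rule for named genes, 20 gene lists defined by search patterns and 13 recalled loci were fixed. The lists cover cellulases, hemicellulases, amylases, other glycoside hydrolases, secondary metabolite backbone enzymes, cytochrome P450 enzymes, conidiation and hydrophobins (markers of asexual structures as against vegetative hyphae), velvet and LaeA family, conidial pigment enzymes, sugar transporters, major facilitator superfamily (MFS) transporters, peptidases, cell wall polymer enzymes, fungal zinc cluster transcription factors, histones and histone modifiers, ribosomal proteins, mitochondrial respiration and TCA cycle, heat shock proteins and chaperones, oxidative stress enzymes, and autophagy and vacuolar degradation. In all, 39 pattern matches to genes of another function were left out, by a choice made after descriptions and a few FPKM values had been seen. The velvet and LaeA family list matched 0 genes, and the zinc cluster list held 2 tested genes. The other 18 lists were tested with limma's camera at a preset inter-gene correlation of 0.01 and again with an estimated correlation, adjusted over lists within a comparison. Gene ontology terms of the deposited table with 10 to 300 tested genes, 147 terms, were tested the same way, a choice made after the data had been seen.

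Named genes were chosen by rule. For each comparison with WT these were, among called genes whose libraries do not overlap between the strains and whose mean FPKM is at least 10 in either strain, the 5 largest rises and the 5 largest falls, the same among described genes, and the 2 called members with the largest absolute change in each of the lists of enzymes, transporters, development, secondary metabolism and histones. Between mutants the 3 largest rises and falls among described genes were taken. PDE_00584, the H2B gene and the recalled loci were always included. Neighbouring calls were compared with 10000 random orders of the tested genes, with locus numbers taken as the gene order. Overlaps between comparisons that share the WT libraries were set beside 100 simulations of unchanged groups with the spread pooled over strains, 100 more with each strain's own spread (added after the data had been seen), and beside the overlap of independent lists.

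The alternatives tried were pseudocounts of 0.1 and 5, no filter and a stricter filter (mean FPKM of at least 5), 3 rescalings (to equal totals as TPM, by the median ratio to the geometric mean library, and by quantiles), only the libraries of the 2 strains compared, the replicate number as a block, and each library left out in turn. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for the other steps.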

Results

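Transcript levels of 9931 genes were measured in mycelia of Penicillium oxalicum, a filamentous fungus that secretes plant cell wall degrading enzymes, 24 h after transfer to a glucose medium. There were 3 libraries each of the wild type (WT), of a strain lacking laeA (DlaeA), and of strains in which lysine 123 or lysine 131 of histone H2B was replaced by alanine (H2BK123A and H2BK131A). LaeA is a putative methyltransferase known in filamentous fungi as a regulator of secondary metabolite clusters and of development, and H2B is a core histone. The study asked what each mutation changes and, as its published aim is recalled, whether the H2B lysines act in the same processes as LaeA. Between 157 and 284 genes per library were listed at an FPKM of 0, 8803 to 9138 genes were at 1 or more, and the median FPKM was 20.5 to 25.1. The 10 highest genes held 8.41% to 13.5% of a library's FPKM.

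The locus recalled as laeA, PDE_00584, was at FPKM 34.9, 37.9 and 33.9 in the WT libraries and at 0.11, 0.05 and 0 in the DlaeA libraries. It averaged 34.3 ± 1.13 (SD, n = 3) in H2BK123A and 37.4 ± 3.24 (SD, n = 3) in H2BK131A, and neither differed from WT (limma, Benjamini-Hochberg adjusted p = 0.687 and 0.558), although with scaling by median ratio the H2BK123A value was called lower (-0.27, adjusted p = 0.0183). Its fall alone does not identify it, since 24 genes had a mean FPKM under 0.5 in DlaeA and at least 10 in each of the other 9 libraries. The H2B gene PDE_01489 was at 1107 ± 75.5 in WT and at 953 ± 55.0 in H2BK123A and 1092 ± 30.1 in H2BK131A (SD, n = 3). A codon change is not visible in such values, so the labels of these strains were not checked. H2B was lower in DlaeA, at 736 ± 52.2 (log2 fold change -0.59 ± 0.13 SE, adjusted p = 0.0015), but not with quantile scaling (-0.30, adjusted p = 0.0712).

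In a principal component analysis across genes the strains separated, with 50.7% of the variance on the first component and 35.1% on the second. The WT libraries varied most, with a median SD per gene of 0.223 on the log2 scale against 0.111 to 0.124 in the mutants. WT 2 stood apart from WT 1 and WT 3, most of all in highly expressed genes. At an FPKM of 30 to 100 the SD of its log2 difference was 0.622 from WT 1 and 0.474 from WT 3. Between WT 1 and WT 3 it was 0.414. At an FPKM of 1000 or more these values were 1.311, 1.139 and 0.439. The libraries DlaeA 2 and DlaeA 3 were closer than any other pair. Over 279 genes with recovered reads they agree within sampling noise (chi-square 290.4, p = 0.308 from a chi-square test of reads), while DlaeA 1 differed from both (p = 7.97e-05 and 7.68e-08). Among 74 genes with an FPKM over 1000 they differed by more than counting noise allows (SD of the log2 difference 0.093 against at most 0.06). They were therefore counted as separate libraries, and averaging them left 6113 called genes for DlaeA against WT.

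In the laeA deletion strain 25 neighbouring genes from PDE_09227 to PDE_09251 fell together (median log2 fold change -8.26), among them genes described as enzymes of dihydroxynaphthalene pigment synthesis, while the gene described as the conidiation regulator BrlA rose. PDE_09236, described as scytalone dehydratase, was at FPKM 1.13 ± 0.91 in DlaeA against 2908 ± 2159.9 in WT (SD, n = 3), a log2 fold change of -9.96 ± 0.69 (limma, adjusted p = 1.78e-07). The nearby tetrahydroxynaphthalene reductase PDE_09239 (-9.46 ± 0.59) and the polyketide synthase PDE_09237, described as that of monodictyphenone (-8.30 ± 0.62), fell with it. Other members are described as a norsolorinic acid ketoreductase (PDE_09231) and an aflatoxin efflux pump (PDE_09228). The descriptions therefore do not settle which product the stretch makes. PDE_00087, the gene described as BrlA, a zinc finger protein that starts conidiophore development in related fungi, was at 435 ± 20.2 against 18.1 ± 11.7 (4.76 ± 0.42, adjusted p = 1.42e-06). In WT 2, PDE_09236 was at 439.7 against 4451 in WT 1 and 3834 in WT 3, and PDE_09239 and PDE_09237 were lower there too.

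The largest changes in DlaeA by the rule for named genes included both transporters and enzymes, and neither transporter list was called (camera adjusted p = 0.108 for MFS and 0.436 for sugar transporters, both adjusted p = 0.927 with an estimated correlation). PDE_03475, described as a sugar:H+ symporter of the MFS family, rose from 1.58 ± 0.58 to 4049 ± 1237 (10.58 ± 0.24, adjusted p = 1.35e-11), and another so described, PDE_09377, fell from 17329.8 ± 1786 to 16 ± 8.9 (-10.11 ± 0.33, adjusted p = 2.88e-10). The Na+-exporting ATPase PDE_03497 (9.63), the oligopeptide transporter PDE_06899 (9.23), the amino acid transporter PDE_00845 (7.78) and the arrestin-related trafficking adapter PDE_08419 (7.68) rose. PDE_05889, described as tryptophanase (-10.03), and the secreted acid protease aspergillopepsin I, PDE_07344 (-9.95), fell. Among genes without a description, PDE_00558 (8.70) and PDE_07434 (8.22) rose, and PDE_06813 (-10.73) and PDE_09235 (-10.14) fell.

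Of 12 amylase genes, which digest starch, 4 rose, 5 fell and 3 were not called in DlaeA. The glucoamylase PDE_09417 dropped from 9352 ± 1391 to 235 ± 162 (-5.73 ± 0.57, adjusted p = 3.55e-06) and PDE_01201, described as an alpha-amylase, fell too (-3.12 ± 0.46), whereas PDE_04454, described as an oligo-1,6-glucosidase, rose (3.04). Of 25 cellulase genes, 10 rose, 9 fell and 6 were not called. The cellobiohydrolase PDE_07945 was at 22.3 ± 0.79 against 25 ± 11.5 (-0.08 ± 0.27, adjusted p = 0.814). The log2 fold change of the endoglucanase PDE_07929 was -0.09 ± 0.23 (adjusted p = 0.756). The beta-glucosidase PDE_02736 fell (-1.78), while PDE_01277 (3.20) and the endoglucanase PDE_05193 (3.09) rose. ClrB (PDE_05999), a known activator of cellulase genes, fell (-1.37 ± 0.10), and its counterpart XlnR (PDE_07674, 0.87), the carbon catabolite repressor PDE_03168 (0.80) and the cellobiohydrolase II PDE_07124 (0.77) rose. Of 80 hemicellulase genes 32 rose and 26 fell, with the arabinofuranosidase PDE_07585 (-7.15) and the mannanase PDE_00051 (6.61) as the widest changes. Of 3 other glycoside hydrolases the GH45 protein PDE_07928 (-3.56) and PDE_00579 (-0.95), described as a glycoside hydrolase family 1 protein, fell. The GH10 xylanase PDE_08094 rose (3.39), with 1 gene up and 2 down in all. The 13 recalled loci hold an alpha-amylase, BrlA and PDE_00584 beside cellulases and regulators. Of them 11 were called over all genes, and 11 adjusted over the list alone, where 69.9% of all tested genes were called. The 11 include PDE_00584, whose call would follow from the deletion if it is laeA.

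Of 15 secondary metabolite backbone genes 8 rose, 3 fell and 4 were not called in DlaeA, with the naphtho-gamma-pyrone polyketide synthase PDE_09491 (4.10) among those that rose. Of 9 cytochrome P450 genes 5 rose and 2 fell, with PDE_04015 (3.13) and PDE_01070 (2.90) higher. Of 4 conidiation genes BrlA, FlbD (PDE_03008, 1.95) and a further gene described as BrlA (PDE_00079) rose, and the spore wall gene DIT1 (PDE_01188) fell (-5.36 ± 1.21, adjusted p = 0.00197), from WT values of 376, 5.93 and 164. The pigment list of 10 genes had 3 up and 3 down. Of its members 7 are described as iron transport multicopper oxidases, enzymes known from iron uptake. PDE_09492 (4.25) and PDE_09453 (2.28) of these rose and PDE_07612 fell (-0.26), and PDE_04496, also described as scytalone dehydratase, rose (5.66), these 4 being named after their values were seen. Of 116 MFS transporters 40 rose and 50 fell, and of 5 sugar transporters 2 rose and 2 fell, the maltose permease PDE_09994 (-2.05) and the cellodextrin transporter CdtD, PDE_00753 (-1.58), being lower. Peptidases (85 genes) had 45 up and 23 down, with the Xaa-Pro dipeptidase PDE_04034 (4.54) and the tripeptidyl-peptidase PDE_01983 (-4.86) as the widest. Cell wall polymer enzymes (77) had 30 up and 31 down, with the exo-beta-1,3-glucanase PDE_08250 (6.95) and the chitin binding protein PDE_03292 (-6.86). Histones and their modifiers (36) had 18 up and 6 down, including the deacetylase HOS3, PDE_05755 (1.31), and the chaperone ASF1, PDE_04869 (1.23). Of the 2 zinc cluster factors PDE_03268 fell (-0.95) and PDE_04246 was not called (-0.01). Ribosomal protein genes (137) had 63 up and 10 down, autophagy genes (46) 27 and 7, mitochondrial genes (86) 21 and 36, oxidative stress genes (37) 17 and 11, and heat shock genes (26) 10 and 5.

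In all, limma called 6596 of 9431 genes in DlaeA against WT (69.9%), 4371 higher and 2225 lower, and 2843 of them by at least 2-fold, 1724 higher and 1119 lower. From the libraries of these 2 strains alone 5843 genes were called. The libraries of the 2 strains did not overlap for 6626 genes (70.3%), where chance gives 10%. None of the 18 lists passed camera (0 called, 2 at an unadjusted p under 0.05), the lowest adjusted p being 0.0595 for mitochondrial genes. Those were called with median ratio (0.00758) and quantile scaling (0.0117), without DlaeA 2 (0.0187) or DlaeA 3 (0.0314), and with DlaeA 2 and DlaeA 3 averaged (0.024). With an estimated correlation 0 lists were called, 0 of them at an unadjusted p under 0.05. Adjusted over the list alone, counts of members differed only for amylases (4 up, 6 down), pigment genes (3 and 2), peptidases (46 and 23) and ribosomal genes (62 and 9). The median of all genes lay at 0.27 and moved to 0.02 with median ratio and 0.10 with quantile scaling, and the share of calls that were higher was 66.3% as deposited, 50.5% and 56.0% under these. At 2-fold or more the balance turned with median ratio (1229 higher, 1459 lower) and was near even with quantile scaling (1346 and 1337). The higher-to-lower balance of members turned for heat shock (7 to 9 with median ratio), hemicellulase (23 to 34) and oxidative stress genes (13 to 15). With median ratio it became near even for ribosomal (37 to 32), peptidase (30 to 29) and histone genes (12 to 11), and was 10 to 48 for mitochondrial and 20 to 10 for autophagy genes. It went from even to 1 up and 3 down for sugar transporters. Relative to the median of all genes, the list medians were 1.28 for conidiation, 0.85 for backbone enzymes, 0.26 for ribosomal, -0.30 for MFS, -0.40 for mitochondrial and -0.66 for amylase genes. Medians lay above 0 while camera pointed down for cell wall, cellulase, pigment, hemicellulase and oxidative stress genes, and the mean was below 0 for cell wall (-0.05), pigment (-0.69) and oxidative stress genes (-0.09).

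**Figure D1:**
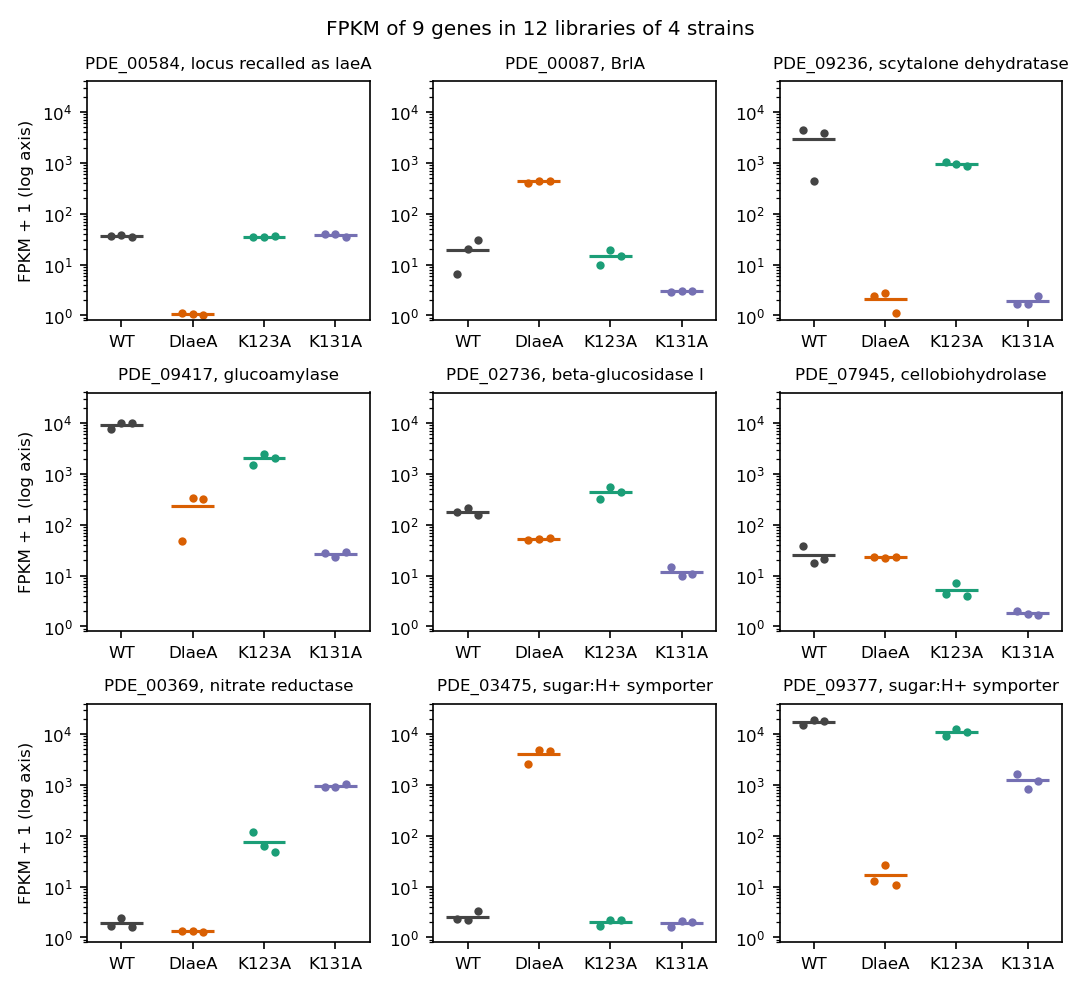
FPKM + 1 on a log axis for 9 genes in the 12 libraries, with each point a library and each line the mean of a strain. PDE_00584 is near 0 in the DlaeA libraries only, BrlA (PDE_00087) is highest in DlaeA, and scytalone dehydratase (PDE_09236) is at 439.7 in WT 2 against 4451 and 3834 in WT 1 and WT 3.

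In H2BK123A genes described as nitrate reductase and nitrite reductase were among those that rose most. The nitrate reductase PDE_00369 was at 74.8 ± 36.9 against 0.92 ± 0.47 in WT (SD, n = 3), a log2 fold change of 5.22 ± 0.27 (limma, adjusted p = 4.13e-07), and the adjacent nitrite reductase PDE_00370 at 178 ± 88.4 against 5.07 ± 3.56 (4.92 ± 0.36, adjusted p = 2.7e-06). A methionine synthase of the cobalamin-independent type, PDE_05422 (5.19 ± 0.30), the tryptophan synthase PDE_02771 (4.54 ± 0.32) and the catechol O-methyltransferase PDE_00009 (4.47 ± 0.50) also rose. The largest fall was that of PDE_06055, a gene without a description (-6.54 ± 0.71, adjusted p = 3.72e-05), at 13.9 ± 2.77 in H2BK123A against 4087, 277 and 2236 in WT 1, WT 2 and WT 3.

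Several of the genes that fell in H2BK123A were also lower in WT 2 than in the other WT libraries. The arabinofuranosidase PDE_07585 fell (-3.78 ± 0.73, adjusted p = 0.0016) from WT values of 1256, 74.9 and 459. The triacylglycerol lipase PDE_09947 (-3.95 ± 0.49), from WT values of 3507, 631 and 2180.1, the Chitinase II PDE_08122 (-3.78 ± 0.50), from 867, 271 and 544, and the xylanase PDE_02682 (-3.42 ± 0.35), from 221, 67.5 and 191, fell too. PDE_02114 (-5.60), PDE_09771 (-4.27), PDE_02200, described as a tyrosyl-DNA phosphodiesterase (-4.43), and PDE_09675, described as actin-related protein 8 (-4.16), completed the largest falls. PDE_09236 (-1.04, adjusted p = 0.243) and PDE_09239 (-1.06, adjusted p = 0.16), described as pigment enzymes, were not called. Nor was BrlA (-0.19, adjusted p = 0.739), although without WT 1 BrlA was called lower (-0.82, adjusted p = 0.0151).

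Of 12 amylase genes 6 rose, 4 fell and 2 were not called in H2BK123A, with PDE_01201 (-3.15 ± 0.46) and the glucoamylase PDE_09417 (-2.23 ± 0.57, adjusted p = 0.00763) lower. Of 25 cellulase genes 7 rose and 6 fell. The cellobiohydrolase PDE_07945 dropped from 25 ± 11.5 to 4.14 ± 1.69 (-2.30 ± 0.27, adjusted p = 6.23e-05) and the endoglucanases PDE_07929 (-0.97) and PDE_09226 (-0.50) fell, while the beta-glucosidase PDE_02736 rose from 181 ± 29.8 to 443 ± 117 (1.26 ± 0.21, adjusted p = 0.000526). The catabolite repressor PDE_03168 (1.02) and XlnR (0.71) rose, whereas ClrB was not called (-0.11, adjusted p = 0.387) except lower with median ratio (-0.33, adjusted p = 0.00592) and quantile scaling (-0.27, adjusted p = 0.0238). Of the 13 recalled loci 7 were called over all genes, and 8 adjusted over the list alone, where 46.6% of all tested genes were called. Hemicellulases had 29 up and 18 down of 80, and other glycoside hydrolases 0 and 1 of 3, PDE_07928 (-2.67). The cell wall list had 25 up and 14 down of 77, with PDE_08122 and the chitinase PDE_01168 (-2.92) as the widest changes, the latter from WT values of 223, 45.2 and 58.2.

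Of 37 oxidative stress genes 24 rose, 3 fell and 10 were not called in H2BK123A (median log2 fold change 0.59, 0.41 relative to all genes, camera adjusted p = 0.00942). This was 1 of 18 lists called, with adjusted p = 0.936 with an estimated correlation, and it was not called without WT 2 (adjusted p = 0.097). Of its members 12 are described as glutathione S-transferases, among them PDE_01194 (3.59) and PDE_00601 (2.32), and the catalase PDE_05708 rose (2.42). These 3 were chosen after their values were seen. MFS transporters had 50 up and 16 down of 116, including PDE_01187 (3.17) and PDE_06397 (2.73). Of 5 sugar transporters 3 rose, among them cdt-g, PDE_09395 (0.73), and the maltose permease PDE_09994 (0.69, adjusted p = 0.0292). That permease was not called with median ratio scaling (0.47, adjusted p = 0.101). Nor was it called when any 1 of WT 1, WT 3 or the H2BK123A libraries was left out (0.61 to 0.73, adjusted p = 0.0547 to 0.0889). Peptidases had 35 up and 8 down of 85, with the aminopeptidase PDE_09121 (2.58) and the carboxypeptidase PDE_05305 (1.76). The cytochrome P450 enzyme PDE_01689 (2.24) and PDE_04015 (1.39) were the 2 that rose of 9, with 1 down. Backbone enzymes had 4 up and 3 down of 15, including PDE_04441 (1.14) up and the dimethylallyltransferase PDE_01066 (-1.48) down, the latter not called from the 2 strains alone (adjusted p = 0.0612). Conidiation genes had 0 called of 4 and pigment genes 1 of 10, the multicopper oxidase PDE_07612 (0.46), which was not called with quantile scaling (0.24, adjusted p = 0.0778). Histones and modifiers had 9 up and 3 down, among them histone H4.2, PDE_08392 (0.98), and the methyltransferase PDE_04196 (-0.87). PDE_04246 rose (1.02) and PDE_03268 was not called (0.23) among zinc cluster factors. Autophagy genes had 23 up and 2 down, mitochondrial genes 17 and 9, heat shock genes 7 and 8, and ribosomal protein genes 11 and 4, the last list not being called over all libraries (adjusted p = 0.771, and adjusted p = 0.936 with an estimated correlation) but called lower without WT 1 (adjusted p = 0.0017).

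In all, 4399 genes (46.6%) were called in H2BK123A against WT, 3160 higher and 1239 lower, and 1291 by at least 2-fold, 882 higher and 409 lower. The libraries did not overlap for 4974 genes (52.7%), where chance gives 10%. Without WT 2 the count was 5229, and without H2BK123A 1 it was 3518. From the libraries of these 2 strains alone it was 3342, 2472 higher and 870 lower. With an estimated correlation camera called 0 lists, 0 of them at an unadjusted p under 0.05. Adjusted over the list alone, member counts became 25 up and 4 down for autophagy, 8 and 6 for cellulases, 1 and 1 for other glycoside hydrolases, 30 and 19 for hemicellulases, 51 and 17 for MFS transporters, 16 and 7 for mitochondrial, 36 and 8 for peptidases, 4 and 2 for ribosomal genes, and 5 and 4 for backbone enzymes. The median of all genes was 0.18 and moved to -0.02 with median ratio and to -0.004 with quantile scaling, and the share of calls that were higher went from 71.8% to 49.5% and 51.2%, and at 2-fold or more from 68.3% to 51.8% and 51.9%. The balance of members turned with median ratio for autophagy (11 up, 12 down), cell wall (13, 25), cellulase (5, 7), P450 (2, 3), histone (6, 9), mitochondrial (11, 25), ribosomal (4, 12) and backbone genes (3, 4), and with quantile scaling for pigment (0, 2) and hemicellulase genes (21, 22). Peptidases had 25 up and 21 down with median ratio and 26 and 18 with quantile scaling, and MFS transporters 43 and 23, and 37 and 25. Camera pointed down while the median lay above 0 for amylases, cell wall, cellulases, other glycoside hydrolases, heat shock, hemicellulases, histones, mitochondrial and ribosomal genes, and the mean was below 0 for amylases (-0.07), cell wall (-0.05) and other glycoside hydrolases (-0.70).

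In H2BK131A 8 of 12 amylase genes and the 5 genes of the sugar transporter list fell, and 126 of 137 ribosomal protein genes and 72 of 86 mitochondrial genes rose (camera adjusted p = 0.00226, 0.00164, 1.19e-14 and 1.74e-09, and adjusted p = 0.439 to 0.462 with an estimated correlation). The sugar transporter list leaves out 24 genes described as sugar:H+ symporters, which are in the MFS list and of which 9 rose, among them PDE_03140 (7.89), 13 fell, among them PDE_03313 (-5.29), and 2 were not called, a count and a gene chosen after the values were seen. The nitrate reductase PDE_00369 was at 946 ± 78.1 against 0.92 ± 0.47 in WT (SD, n = 3), a log2 fold change of 8.97 ± 0.27 (limma, adjusted p = 4.94e-10). The nitrite reductase PDE_00370 (8.57 ± 0.36) and the nitrate/nitrite transporter PDE_00371 (6.83 ± 0.19) next to it rose as well. The glucoamylase PDE_09417 dropped from 9352 ± 1391 to 25.8 ± 2.76 (-8.44 ± 0.57, adjusted p = 1.11e-07). Scytalone dehydratase (PDE_09236) was at 0.94 ± 0.39 against 2908 ± 2159.9, with the WT 2 value at 439.7 (-10 ± 0.69, adjusted p = 1.39e-07).

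Other genes with large rises in H2BK131A were the oleate hydratase PDE_01480 (8.82 ± 0.44), the lactate dehydrogenase PDE_01482 (8.42 ± 0.35), the sugar:H+ symporter PDE_03140 (7.89 ± 0.25), and the genes PDE_04041 (9.37) and PDE_01479 (9.04), which have no description. Next to PDE_09236, the genes PDE_09235 (-8.92), PDE_09233 (-8.70), the aflatoxin efflux pump PDE_09228 (-8.44), the reductase PDE_09239 (-8.26) and the polyketide synthase PDE_09237 (-7.62) fell. So did PDE_06813 (-9.54) and the cutinase PDE_03294 (-8.21).

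Of 12 amylase genes 8 fell, 1 rose and 3 were not called in H2BK131A (median -1.60, camera adjusted p = 0.00226, and adjusted p = 0.462 with an estimated correlation). PDE_01201 (-7.71 ± 0.46), the alpha-glucosidase PDE_04151 (-5.76) and the glucoamylase PDE_05527 (-5.10) were among those that fell, the last 2 named after their values were seen. The 5 genes of the sugar transporter list, which holds none of the symporters of the MFS list and includes PDE_06433, described as a quinate transporter, fell, by log2 fold changes of -1.08 to -4.57, including the maltose permease PDE_09994 (-4.57) and CdtD, PDE_00753 (-3.76) (camera adjusted p = 0.00164, and adjusted p = 0.439 with an estimated correlation). Of 25 cellulase genes 10 rose and 13 fell (adjusted p = 0.146). The beta-glucosidase PDE_02736 (-3.96), the cellobiohydrolases PDE_07945 (-3.75) and PDE_07124 (-1.17), and the endoglucanases PDE_09226 (-1.91) and PDE_07929 (-1.10) were lower. The cellulase list was called without H2BK131A 1 (adjusted p = 0.0308) or H2BK131A 3 (0.0381), and with excluded matches kept (0.045), while over all libraries it had adjusted p = 0.641 with an estimated correlation. PDE_03964, a recalled locus without a description (-3.12), XlnR (-0.88), ClrB (-0.41) and the catabolite repressor PDE_03168 (-0.51, adjusted p = 0.0229) fell, the repressor not being called without WT 2 (adjusted p = 0.0813), without H2BK131A 2 (0.0979) or from the 2 strains alone (0.0566). PDE_00579 rose (0.61), and 12 of the 13 recalled loci were called over all genes and 12 adjusted over the list alone, where 70.8% of all tested genes were called. Hemicellulases had 23 up and 37 down of 80 (adjusted p = 0.085, and 0.0328 without H2BK131A 1, with adjusted p = 0.752 over all libraries with an estimated correlation), with the xylanase PDE_09478 (6.08) and the arabinofuranosidase PDE_07585 (-4.69) as the widest. Of the 3 other glycoside hydrolases 2 rose and 1 fell (PDE_07928, -2.10), and the rise of PDE_08094 (0.66) was lost with a pseudocount of 5 (adjusted p = 0.0997) and quantile scaling (0.184).

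Of 137 ribosomal protein genes 126 rose and 2 fell in H2BK131A, with a median log2 fold change of 1.88, or 1.75 relative to all genes (camera adjusted p = 1.19e-14, adjusted p = 0.439 with an estimated correlation). The rises reached 3.01 in PDE_00779, described as L10Ae, and the falls were those of PDE_02709 (-1.04) and PDE_00150 (-0.70), all 3 named after their values were seen. Of 86 mitochondrial respiration and TCA cycle genes 72 rose and 0 fell (median 0.90, adjusted p = 1.74e-09, and adjusted p = 0.439 with an estimated correlation). Among those chosen after their values were seen were the cytochrome c oxidase assembly subunit PDE_08885 (4.01), the fumarate hydratase PDE_03394 (2.45) and the citrate synthase PDE_09135 (2.13). The homoisocitrate dehydrogenase PDE_05183 (2.94), the homocitrate synthase PDE_03916 (2.11) and the homoaconitase PDE_02592 (1.96), also in that list, act in lysine synthesis. Of 37 oxidative stress genes 25 rose and 5 fell (median 1.30, adjusted p = 0.00164), and of 26 heat shock and chaperone genes 18 rose and 3 fell (median 0.61, adjusted p = 0.0195). Both had adjusted p = 0.439 with an estimated correlation. Autophagy genes had 9 up and 17 down of 46 (median -0.16, adjusted p = 0.0377, adjusted p = 0.752 with an estimated correlation), and the call was lost without WT 2 (0.0737) or H2BK131A 2 (0.0507).

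Of 10 pigment genes 7 fell and 3 rose in H2BK131A (median -1.58, adjusted p = 0.045, adjusted p = 0.439 with an estimated correlation). The 7 multicopper oxidases of iron transport included 3 that rose. The call was lost with each rescaling (median -1.63 to -1.75, adjusted p = 0.0756 to 0.138), without WT 3 (0.0631), without DlaeA 1 (0.0529) and with the excluded matches kept in the lists (0.125). MFS transporters had 45 up and 60 down of 116 (median -0.60, adjusted p = 0.0446, adjusted p = 0.616 with an estimated correlation). This call was also lost with each rescaling (median -0.68 to -0.79, adjusted p = 0.0788 to 0.188), without WT 1 (0.0584) and without WT 3 (0.062). FlbD (PDE_03008, -3.96 ± 0.23) and BrlA (PDE_00087, at 2.01 ± 0.09 against 18.1 ± 11.7, -2.42 ± 0.42) fell, and the other 2 conidiation genes were not called. Backbone enzymes had 6 up and 6 down of 15, among them the naphtho-gamma-pyrone synthase PDE_09491 (5.28), and P450 enzymes 5 up and 3 down of 9, among them PDE_01689 (4.79) and PDE_01418 (-3.03). The cell wall list had 31 up and 17 down of 77, with the chitin glucanosyltransferase PDE_07531 (7.21) and the chitinase PDE_01168 (-5.56). Peptidases had 34 up and 24 down of 85, with ClpB, PDE_00424 (3.72), which is a chaperone that dissolves protein aggregates. Histones and modifiers had 14 up and 5 down of 36, with the deacetylase HOS2, PDE_07341 (0.93), and the deacetylase complex subunit SAP18, PDE_00041, higher. Of the zinc cluster factors PDE_03268 fell (-0.39) and PDE_04246 rose (0.46, adjusted p = 0.0177). The rise of PDE_04246 was lost with median ratio (0.0556), from the 2 strains alone (0.0599) and without WT 1 (0.0575), WT 3 (0.0555) or H2BK131A 1 (0.0806).

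In all, 6675 genes (70.8%) were called in H2BK131A against WT, 3831 higher and 2844 lower, and 3163 by at least 2-fold, 1875 higher and 1288 lower. From the libraries of these 2 strains alone 6005 genes were called. The libraries did not overlap for 6653 genes (70.5%), where chance gives 10%. Camera called 9 of 18 lists and, with an estimated correlation, 0 (0 at an unadjusted p under 0.05). Adjusted over the list alone, member counts differed for autophagy (8 up, 17 down), hemicellulases (23, 38), mitochondrial genes (74, 0), peptidases (32, 24) and ribosomal genes (127, 2). The median of all genes was 0.13, -0.03 with median ratio and 0.004 with quantile scaling. The balance of calls turned with median ratio (3326 higher, 3542 lower) and was near even with quantile scaling (3396 and 3318), and at 2-fold or more it was 1587 to 1567 and 1568 to 1496. The balance of members turned with median ratio for histones (9 up, 12 down) and peptidases (29, 30), backbone genes went from even to 5 and 7, autophagy genes had 5 and 30, and no called list changed direction under any rescaling. The mean was below 0 (-0.28) and the median above 0 (0.61) for other glycoside hydrolases.

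**Figure D2:**
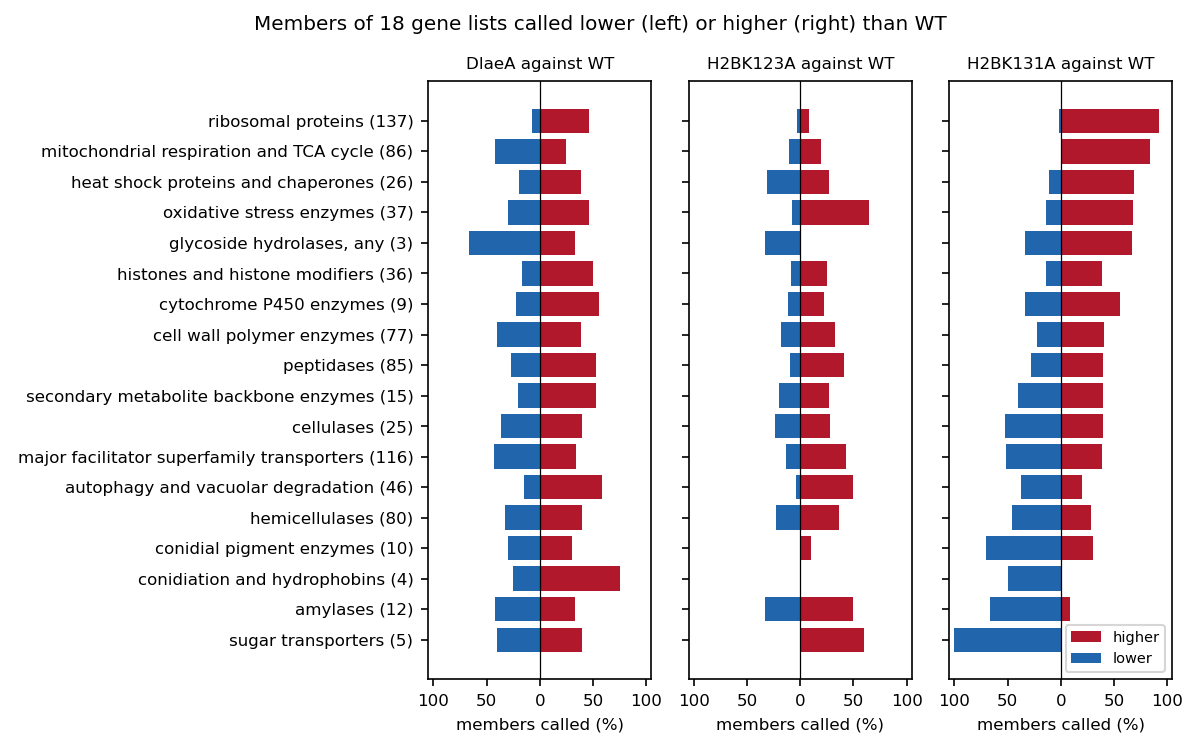
Percentage of the members of 18 gene lists called higher or lower than WT in each mutant, with the number of members in brackets. In H2BK131A 126 of 137 ribosomal protein genes are higher and the 5 genes of the sugar transporter list lower (24 sugar:H+ symporters of the MFS list, 9 higher and 13 lower, are not among them), while with median ratio scaling the balance turns for heat shock, hemicellulase and oxidative stress genes in DlaeA, for 8 lists in H2BK123A (with quantile scaling also for pigment and hemicellulase genes) and for histones and peptidases in H2BK131A.

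The mutants were also compared with one another, to test differences directly. H2BK123A differed from DlaeA in 5768 genes (61.2%), 2646 higher and 3122 lower in H2BK123A, with 1298 higher and 1101 lower at 2-fold or more. The split was even with median ratio scaling (2943 and 2950) and was 2688 higher to 3286 lower with quantile scaling. The symporter PDE_09377 (9.43 ± 0.33), the glutathione S-transferase PDE_01194 (9.39 ± 0.37) and scytalone dehydratase, at 957 ± 77.5 in H2BK123A (PDE_09236, 8.92 ± 0.69), were the highest in H2BK123A, and PDE_03475 (-10.92 ± 0.24), PDE_06899 (-9.31 ± 0.21) and PDE_03497 (-9.26 ± 0.23) the lowest. MFS transporters (60 higher, 29 lower of 116, median 0.60 relative to all genes) and oxidative stress genes (20 and 6 of 37, 0.61) were called by camera (adjusted p = 0.00925 for both, adjusted p = 0.885 for both with an estimated correlation). Ribosomal protein genes were not called over all libraries (adjusted p = 0.298, and adjusted p = 0.885 with an estimated correlation) but were called lower without WT 1 (adjusted p = 0.011). The libraries did not overlap for 74% of genes, 83.4% between H2BK131A and DlaeA and 78.5% between the H2B mutants, where chance gives 10%.

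H2BK131A differed from DlaeA in 7308 genes (77.5%), 3416 higher and 3892 lower in H2BK131A, and from H2BK123A in 6479 genes (68.7%), 3107 higher and 3372 lower. The first balance turned with median ratio (3747 higher, 3645 lower) and was 3607 to 3747 with quantile scaling, and the second turned with quantile scaling (3393 and 3235) and was 3304 to 3314 with median ratio. Against DlaeA the nitrite reductase PDE_00370 (10.28 ± 0.36), PDE_01194 (10.26 ± 0.37) and the nitrate reductase PDE_00369 (9.47 ± 0.27) were the highest, and PDE_03475 (-11.01 ± 0.24), the acyl-carrier protein reductase PDE_04495 (-9.45 ± 0.45) and PDE_00845 (-9.07 ± 0.18) the lowest. Against H2BK123A the symporter PDE_03140 (5.85 ± 0.25), the lactate dehydrogenase PDE_01482 (5.72 ± 0.35) and the xylanase PDE_09478 (5.50 ± 0.17) were the highest, and scytalone dehydratase (-8.97 ± 0.69), the cutinase PDE_03294 (-8.14 ± 0.23) and the D-arabinitol dehydrogenase PDE_05532 (-7.77 ± 0.27) the lowest. Ribosomal protein genes were higher in H2BK131A than in either other mutant (125 higher, 6 lower against DlaeA, adjusted p = 2.23e-12, and 126 and 6 against H2BK123A, adjusted p = 1.8e-18), with adjusted p = 0.626 and 0.484 with an estimated correlation. So were mitochondrial genes (69 and 4, adjusted p = 2.23e-10, and 71 and 2, adjusted p = 8.15e-12) and oxidative stress genes (24 and 4, adjusted p = 0.00022, and 19 and 8, adjusted p = 0.0202, the last lost with quantile scaling at 0.104). With an estimated correlation these had adjusted p = 0.626 for both against DlaeA, and 0.484 and 0.553 against H2BK123A. Amylases (1 and 10, adjusted p = 0.0265, and 0 and 10, adjusted p = 0.000865), sugar transporters (0 and 5 in both, adjusted p = 0.0235 and 0.00209) and autophagy genes (5 and 28, adjusted p = 0.0235, and 4 and 28, adjusted p = 0.00673) were lower. With an estimated correlation these 3 had adjusted p = 0.659, 0.626 and 0.82 against DlaeA, and 0.507, 0.484 and 0.606 against H2BK123A. The autophagy call against DlaeA was lost with quantile scaling (0.0672). With the excluded matches kept in the lists, the amylase and sugar transporter calls were lost against DlaeA (0.672 and 0.29) and against H2BK123A (0.0805 for both). Heat shock genes were higher than in H2BK123A (17 and 5 of 26, adjusted p = 0.00673, and adjusted p = 0.484 with an estimated correlation). Over all libraries cellulases were not called in H2BK131A against DlaeA or H2BK123A (camera adjusted p = 0.0851 and 0.131), nor MFS transporters against H2BK123A (0.075). Cellulases were called lower in both comparisons when any 1 of the H2BK131A libraries was left out (adjusted p = 0.02 to 0.0378), and MFS transporters than in H2BK123A (0.0208 to 0.0251). With an estimated correlation over all libraries the cellulases had adjusted p = 0.659 and 0.572 and the MFS transporters 0.572.

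Genes called in pairs of mutants were compared by direction, where the shared WT libraries mean that independent lists are not the value without a change. Of 3370 genes called in both DlaeA and H2BK123A, 2782 had the same direction (1757 for independent lists) and 588 opposite ones (1320). The same direction held for 3003 of 4680 genes of DlaeA and H2BK131A (2447 for independent lists, with 1677 opposite against 2222) and for 2517 of 3256 genes of H2BK123A and H2BK131A (1657, with 739 against 1456). Unchanged groups simulated against the same WT libraries shared at most 1 call with the spread pooled over strains, and at most 42 with each strain's own spread, a simulation added after the data were seen because WT varied most. No gene was changed in these simulations, so few passed the adjustment. Their shared counts therefore do not measure what the shared WT libraries add where many genes are called. Over all tested genes, 69.1%, 59% and 63.7% had the same sign in these 3 pairs, against 66.6%, 66.8% and 66.7% in unchanged groups simulated with pooled spread and 75.6%, 75% and 75.7% with own spread, so all 3 shares were below the latter. Across genes, which are not independent replicates, the fold changes correlated with r = 0.40, 0.287 and 0.477, where simulated unchanged groups gave 0.498, 0.501 and 0.501 with pooled spread and 0.795, 0.789 and 0.799 with own spread. The covariances were 0.446, 0.619 and 0.519, against 0.018 in each simulation with pooled spread and 0.049 with own spread. The shared WT libraries can add to these overlaps, and 3 libraries do not split into sets of at least 2. In all 3 mutants 1106 genes were higher than WT and 482 lower, 172 and 184 of them by at least 2-fold in each. These counts are of FPKM as deposited, where the median of all genes lay at 0.27, 0.18 and 0.13. With median ratio scaling it lay at 0.02, -0.02 and -0.03. The counts were not repeated under a rescaling, so their tilt to higher genes may depend on the scaling.

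Called genes were next to one another along the locus numbers more often than in random orders. In DlaeA 50.8% of called genes had a next gene called in the same direction (random mean 38.7%, highest 40.4%), in H2BK123A 39.0% (27.8%, 30.1%) and in H2BK131A 47.0% (36.2%, 38.2%), each with a permutation p of 0.0001, the smallest that 10000 orders can give. Windows of 5 genes with at least 3 calls in 1 direction numbered 5478, 2731 and 5284, against at most 5074, 2333 and 4850 in random orders. Genes are not independent replicates, so this describes these calls only. Stretches of at least 5 neighbours changed by at least 2-fold numbered 22 higher and 22 lower in DlaeA, 4 and 3 in H2BK123A, and 17 and 13 in H2BK131A. The longest ran from PDE_09227 to PDE_09251 in DlaeA (25 genes, median -8.26) and from PDE_09226 to PDE_09246 in H2BK131A (21 genes, median -7.53). Both lie around the genes described as pigment enzymes, whose WT 2 values were low. A stretch that starts with PDE_01212, described as brevianamide F synthase, a nonribosomal peptide synthetase, fell in DlaeA (9 genes, median -4.00) and H2BK123A (12 genes, -3.14). PDE_01212 was at 736, 65.3 and 705 in WT 1, WT 2 and WT 3. In DlaeA the stretch from PDE_01061 to PDE_01077 with 2 genes so described rose (15 genes, 3.87), as did that from PDE_09999 to PDE_10010 with a paspaline synthase (PDE_10000) and a hybrid polyketide synthase (PDE_10006) (12 genes, 2.96). In H2BK131A the genes from PDE_09999 to PDE_10003, with the paspaline synthase, fell instead (5 genes, -2.41).

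**Figure D3:**
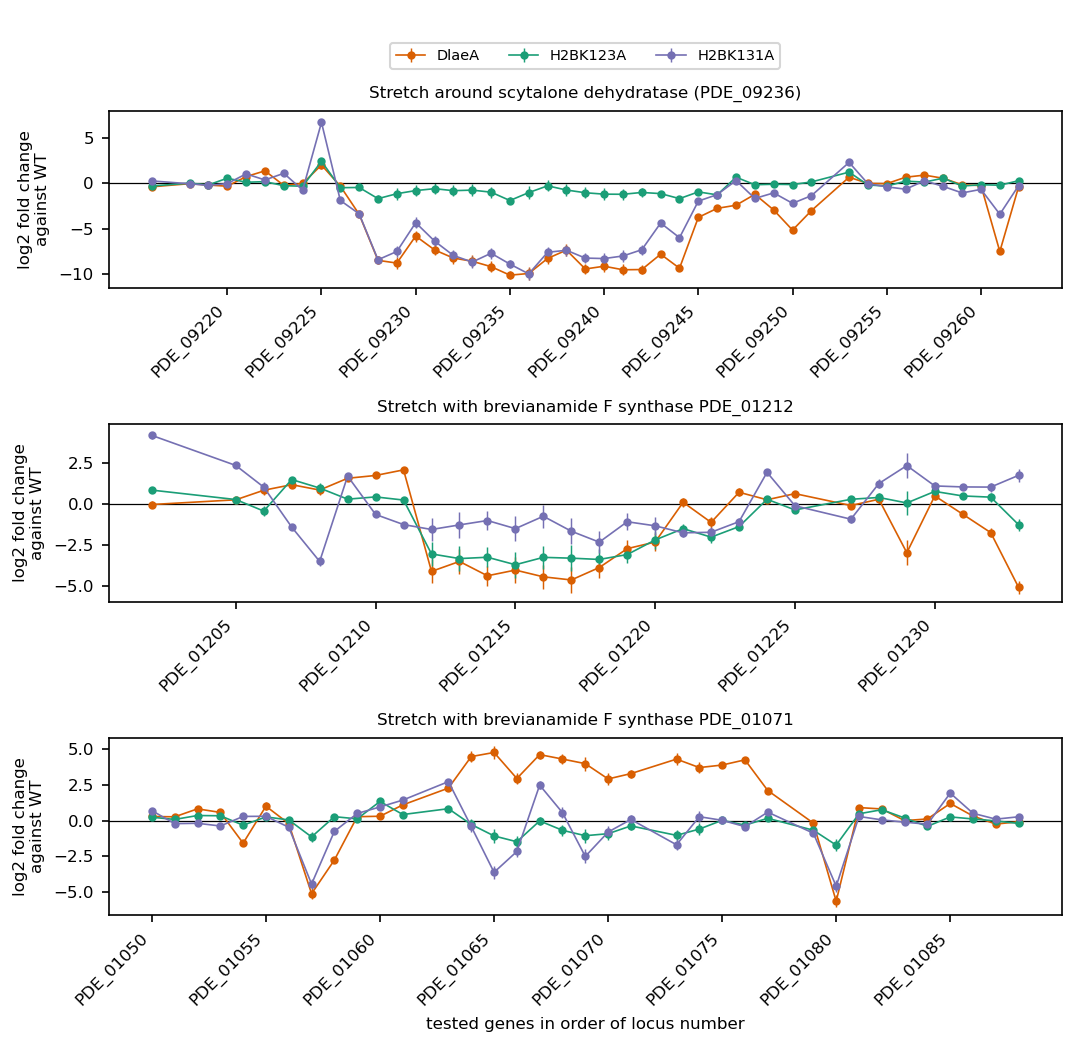
Log2 fold change against WT, on the log2(FPKM + 1) scale with SE bars, of the tested genes along 3 stretches of locus numbers in DlaeA, H2BK123A and H2BK131A. The stretch around PDE_09236 is far below WT in DlaeA and H2BK131A, that with PDE_01212 is lower in DlaeA and H2BK123A, and that with PDE_01071 is higher in DlaeA.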

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

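The comparisons between mutants behind this part were planned, and the genes named as examples were chosen after their values were seen. DlaeA and H2BK123A moved 113 genes in opposite directions by at least 2-fold each, 33 higher and 80 lower in DlaeA. Each of the genes counted in this part also differed between the 2 mutants themselves (limma, Benjamini-Hochberg adjusted p under 0.05), which follows largely from the way they were chosen. The glutathione S-transferase PDE_01194 fell in DlaeA (-5.80) and rose in H2BK123A (3.59), with adjusted p = 1.56e-09 for the difference, and the carboxypeptidase PDE_05305 (-4.19 and 1.76) and the catalase PDE_05708 (-1.77 and 2.42) did likewise. The MFS transporter PDE_06880 (4.25 and -1.56), the salicylate hydroxylase PDE_07956 (4.46 and -1.29) and the indoleamine 2,3-dioxygenase PDE_05907 (3.02 and -1.56) went the other way.

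DlaeA and H2BK131A moved 378 genes apart in this way, 238 higher and 140 lower in DlaeA. The gene described as the conidiation regulator BrlA (PDE_00087) rose in DlaeA and fell in H2BK131A (4.76 and -2.42, adjusted p = 2.27e-08 for the difference), and so did FlbD (PDE_03008, 1.95 and -3.96). The amino acid transporter PDE_00845 (7.78 and -1.29), the scytalone dehydratase PDE_04496 (5.66 and -2.53) and PDE_04495, described as an acyl-carrier protein reductase (4.79 and -4.66) went the same way. The nitrite reductase PDE_00370 (-1.71 and 8.57), the nitric oxide dioxygenase PDE_01345 (-3.67 and 3.46), the NADP-dependent glutamate dehydrogenase PDE_06117 (-2.07 and 5.29) and the pyruvate decarboxylase PDE_04873 (-1.05 and 5.59) were lower in DlaeA and higher in H2BK131A.

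H2BK123A and H2BK131A moved 91 genes apart, 83 higher and 8 lower in H2BK123A. The beta-glucosidase PDE_02736 rose in H2BK123A and fell in H2BK131A (1.26 and -3.96, adjusted p = 4.15e-09 for the difference), as did the oxoglutarate carrier PDE_08879 (1.24 and -6.36), the sugar:H+ symporter PDE_00771 (1.28 and -3.98), the alpha glucoside symporter PDE_01853 (1.79 and -2.99) and the ACV synthetase PDE_03488, which makes the tripeptide precursor of penicillins (1.87 and -2.31). The chitinase PDE_06566 (-2.09 and 1.33) and the chitin binding protein PDE_06567 (-1.90 and 1.75) went the other way.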

How the results depend on the processing

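Averaging DlaeA 2 and DlaeA 3, keeping the excluded matches in the lists and leaving out libraries for the list tests were chosen after the data were seen, and the other settings before the data were examined. With another pseudocount, filter or scaling, or from only the 2 strains compared, the counts of called genes (limma, Benjamini-Hochberg) were 5843 to 6712 for DlaeA against WT, 3342 to 4453 for H2BK123A and 5950 to 6868 for H2BK131A, each within 1.5 times the reported count. At 2-fold or more they were 2070 to 3243, 883 to 1654 and 2326 to 3560, with a pseudocount of 5 the lowest and of 0.1 the highest in each. Leaving out 1 library gave 6054 to 6916 genes (2701 to 3089 at 2-fold) for DlaeA, 3518 to 5229 (1166 to 1656) for H2BK123A and 6074 to 6820 (3035 to 3279) for H2BK131A, 5159 to 6259 for H2BK123A against DlaeA, 6800 to 7605 for H2BK131A against DlaeA and 5879 to 6854 for H2BK131A against H2BK123A. Without 1 library the genes called in the same direction numbered 2187 to 3503 for DlaeA and H2BK123A, 2703 to 3392 for DlaeA and H2BK131A and 2025 to 3117 for H2BK123A and H2BK131A, the highest of each being without WT 2. Averaging DlaeA 2 and DlaeA 3 gave 6113, 4180 and 6556 genes against WT. From only the 2 strains compared, 5843, 3342 and 6005 genes were called against WT, fewer than in the fit over all libraries. Between mutants 6414, 7624 and 7059 were called, more than the 5768, 7308 and 6479 of that fit. The fit over all libraries uses 1 spread per gene for all strains, although WT varied most. Of the calls over gene and comparison pairs named by the rule, 146 to 151 were made under these settings against 150, and of calls at recalled loci 28 to 32 against 30. Most pairs named by the rule were chosen for large called changes in these data, so that they stayed called is little support. With the stricter filter (146) the missing calls were of genes that the filter removed.

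Camera called 25 of 108 pairs of list and comparison with its preset correlation and 0 with an estimated correlation, where 1 was at an unadjusted p under 0.05. The 2 runs differed only in this correlation. In the called lists it was estimated at 0.033 (heat shock genes) to 0.597 (sugar transporters), above the preset 0.01, with 0.434 for ribosomal and 0.261 for mitochondrial genes. Why the members of a list varied together was not tested. With 1 library left out camera called 23 to 30 pairs at the preset correlation. Of the 25 calls, 19 were kept under the 3 rescalings, the replicate block and each left-out library. Calls not given above that changed were those of H2B (PDE_01489), called lower in H2BK123A with median ratio scaling (adjusted p = 0.0117), of PDE_00579, called higher in H2BK123A with a pseudocount of 5 (0.0468), a stricter filter (0.046) and without WT 2 (0.0184), and of PDE_09226, not called in DlaeA from the 2 strains alone (0.0813), without WT 1 (0.0772) or without DlaeA 1 (0.0948). With the replicate number as a block 6489, 4195 and 6567 genes were called against WT, and 5623, 7214 and 6359 between mutants, and no call of a named gene or list changed. The numbers do not pair the libraries: the deviations of 18 same-numbered pairs correlated with r from -0.224 to 0.211, 3 of them over 0.1, and 0 libraries correlated best with their own number in every other strain. Counted over calls of at least 2-fold, the shares of genes with a next gene called in the same direction were 34.2% in DlaeA, 22.9% in H2BK123A and 32.4% in H2BK131A, against at most 18.1%, 11.1% and 19.5% in random orders. Reads could be recovered for some low genes only, so for the other genes the counting error is not known gene by gene.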

Other observations

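The tests of the GO terms, of the difference between WT libraries, and of the library scaling and the highest genes behind the ribosomal rise were chosen after the results were seen, as were the genes and stretches named here. Among the 172 genes at least 2-fold higher in each mutant (limma, adjusted p under 0.05) were 3 of the 4 genes described as HSP20 proteins, small heat shock chaperones. PDE_00175 rose by log2 fold changes of 3.80 in DlaeA and 3.96 in H2BK123A and further in H2BK131A, PDE_02505 by 3.51 and 3.25, and 3.40 in H2BK131A, and PDE_02095 by 3.48, 3.20 and 6.29, while the fourth, PDE_00322, fell in DlaeA (-1.92) and rose in the H2B mutants (1.40 and 3.74). Homogentisate dioxygenase PDE_08906 (4.02, 1.81 and 5.57) and fumarylacetoacetase PDE_08907 (4.26, 1.65 and 5.55), which act in tyrosine breakdown, the alternative oxidase PDE_08849 (2.97, 2.44 and 3.81) and isocitrate lyase PDE_08297, an enzyme of the glyoxylate cycle (1.89, 2.09 and 1.83), rose too. Among the 184 genes lower in each were formate dehydrogenase PDE_01080, at FPKM 4904 ± 420 in WT against 98.4 ± 8.92, 1838 ± 1414 and 206 ± 35.5 (SD, n = 3), and PDE_08282, described as a CreA/MIG zinc finger protein (-4.27, -2.81 and -3.32).

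Neighbouring genes from PDE_07204 to PDE_07208, with a geranylgeranyl diphosphate synthase (PDE_07205), fell by at least 2-fold in each mutant, with medians of -6.90 in DlaeA and -1.86 in H2BK123A, and of -3.11 over a stretch in H2BK131A that starts at PDE_07203. A stretch with oleate hydratase (PDE_01480) and lactate dehydrogenase (PDE_01482) rose in H2BK123A (5 genes, median 2.70) and H2BK131A (7 genes, 7.99), and 5 genes from PDE_08070 with phytoene synthase and desaturase, enzymes of carotenoid synthesis, rose in H2BK123A (1.86). Of 147 GO terms in H2BK131A against WT, camera called 33 higher and 4 lower with its preset correlation and 0 with an estimated correlation, where 1 was at an unadjusted p under 0.05. Of 34 tRNA aminoacylation genes 31 rose and 1 fell (median 1.33, adjusted p = 9.7e-06), and of 19 genes of glucose catabolism 15 rose and 2 fell (1.61, adjusted p = 0.0016). Of 24 genes of polysaccharide catabolism 3 rose and 15 fell (-0.78, adjusted p = 0.0102). These 3 had adjusted p = 0.845 with an estimated correlation. In DlaeA 0 terms were called by camera (20 at an unadjusted p under 0.05), and in H2BK123A 1, cofactor binding, with 18 of 27 genes higher (adjusted p = 0.0177, adjusted p = 0.995 with an estimated correlation).

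Changes in H2BK123A depended on the WT libraries, and to a lesser extent so did the rises in the other mutants. With the 9431 tested genes kept when a WT library was held out, 515 genes were called at least 2-fold lower than WT 1 and WT 3, of which 43.7% were at least 2-fold lower than the held-out WT 2, against 68.9% and 85.4% with WT 1 or WT 3 held out, and of 1146 genes called higher, 43.1% were at least 2-fold higher than WT 2, against 84% and 90.5%. In DlaeA 65.1%, 88.3% and 91.6% of rises were at least 2-fold against a held-out WT 2, WT 1 and WT 3. In H2BK131A these shares were 76.1%, 86.7% and 94.8%. For falls they were 78.3%, 84.8% and 83.6% in DlaeA, and 82.7%, 81.1% and 82.5% in H2BK131A. Across genes, which are not independent replicates, the difference of WT 2 from 1 WT library correlated with that of H2BK123A from the other (average r = 0.505, against 0.327 for DlaeA and 0.159 for H2BK131A). Both go with spread among the WT libraries, with WT 2 apart, as part of the size of the changes in H2BK123A. In H2BK123A 88.5% of the falls and 98.1% of the rises kept their direction against WT 2. An effect of the mutation stays open for the direction as for the rest of the size.

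The rise of ribosomal protein genes in H2BK131A was set against 3 technical explanations. Its median log2 fold change was 1.81 as TPM, 1.70 with median ratio and 1.622 with quantile scaling. The rise was thus kept under each of these scalings. TPM and median ratio multiply each library by 1 factor and moved the median of all genes only from 0.13 to 0.07 and -0.03. Such a shift could not have removed the rise, so they do not test scaling as a cause. The median of the list was at least 1.675 without any 1 WT library, which argues against a single WT library. The 10 highest genes held 12.3% ± 1.22 of FPKM in WT and 8.48% ± 0.10 in H2BK131A (SD, n = 3), a difference of 3.81 percentage points. They thus did not take most of the FPKM in either strain. The limit for the difference was set after the results were seen and was out of reach for such shares, so the difference itself decides nothing. Other technical causes were not tested, and a difference in growth state of the strain may remain as a hypothesis that was not tested either. The list was not called with an estimated correlation (camera adjusted p = 0.439).

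The covariance of the changes between mutants was set against the WT libraries that the mutants share. With a different WT library for each mutant the covariance across genes averaged 0.571 for DlaeA and H2BK131A, 0.399 for DlaeA and H2BK123A and 0.472 for H2BK123A and H2BK131A over 6 assignments, where no WT library is in both differences. This argues against the spread of single WT libraries as the whole cause. A state common to all WT libraries would be in both differences, so the test cannot speak to it. Such a state, or a common effect of the mutations or of making the mutants, stays open and was not tested.

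Each comparison has 10 splits of its 6 libraries, too few for a share under 0.05. In each, the real split was the only 1 with as many genes, at 6596 (2843 at 2-fold) for DlaeA against WT, 4399 (1291) for H2BK123A, 6675 (3163) for H2BK131A, 5768 for H2BK123A against DlaeA, 7308 for H2BK131A against DlaeA and 6479 for H2BK131A against H2BK123A. The highest of the other splits called 0 genes, and 1 for H2BK131A against H2BK123A. Each of these splits mixes libraries of both strains, so a strain difference itself widens the spread and lowers the calls. Their counts are therefore no estimate of calls without a difference.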
